A study of Salmo salar with 37 samples.

How the data were processed

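The data are RNA sequencing of poly(A)-selected transcripts from the distal intestine and the head kidney of farmed Atlantic salmon (Salmo salar) given feed with 0, 4 or 8% meal of black soldier fly larvae. The head kidney is the main blood-forming and immune organ of bony fish, and the distal intestine is the hind part of the gut. The 36 libraries used came from 18 fish, 6 per diet, each with 1 library of each tissue. Tissue and diet were taken from the labels. The design text speaks of 10 fish per diet, and a distal intestine sample of fish 24 (4% diet) has a label but was not analysed here. Fish numbers are shared between the tissues and name the same animals, so they pair the libraries across tissues. Within a diet the fish fall in 2 runs of 3 neighbouring numbers, 6 runs in all, and the labels do not say whether a run marks a cage, a day or nothing.

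Per the labels' protocols, tissue was lysed by bead milling in QIAzol, RNA was extracted with chloroform and isopropanol, and poly(A) RNA was reverse transcribed. Each deposited file holds raw counts of 1 library, made by the authors with featureCounts per the file headers, with no normalization. The headers give program version 1.5.1 and a program folder named for subread 2.0.0, and this discrepancy was left open. Fragments were counted per gene on exons with the reversely stranded setting (option 2) and the paired-end option in all 36 libraries, against the annotation of the Ssal_v3.1 assembly. The aligner is not given in the sources used here. Reads that match several places equally well are not counted by default by this program, so near-identical gene copies, which are frequent in the duplicated salmon genome, can be undercounted. Strand was used in the counting, so antisense partners were told apart. The headers also name 2 storage locations of the alignments, which was tried as a covariate. Each file lists 61216 genes, of which 53947 were found in the reference table of the same assembly, and 16391 have a symbol other than a bare locus number. The files list 0 mitochondrial genes.

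Total counts per library ranged from 11.673 to 18.596 M (mega) counts in distal intestine (median 14.725) and from 11.413 to 17.483 M counts in head kidney (median 13.336). All intervals and floors given cover counting error or the spread between fish as stated, and a floor is the level of 3 counts in a library. CPM, the counts of a gene scaled to the library total, were computed with TMM scaling factors within each tissue, which lay between 0.8649 and 1.144 in distal intestine and between 0.942 and 1.064 in head kidney. CPM in sentences that compare the tissues come from 1 scaling over both tissues, on which the values of the same library can differ from those within a tissue.

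Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after filterByExpr by diet, with robust dispersion and all 3 diets of a tissue in 1 fit, which leaves 15 residual degrees of freedom. The comparisons were 8% with 0%, 4% with 0%, 8% with 4%, and the slope of log2 expression per 1% of insect meal. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Both tissues were fitted together for the diet-by-tissue difference and for the comparison of the tissues, where an absolute log2 difference over 1 was also asked. Log2 differences carry their standard error (SE). Gene lists for 31 pathways and cell types were tested with fry of limma 3.58.1 on voom log2 CPM, 24 per tissue with at least 5 measured members, and adjusted over the lists of a comparison. The mean log2 difference of a list is on the voom scale, where the fish are averaged on the log scale, and the counts of members higher or lower come from edgeR. fry asks whether a list moves on balance in 1 direction, allows for correlation between the members and does not set the list against other genes. The alternative test camera does set a list against the other genes, so it asks a different question. Lists with fewer than 5 measured members were not tested. These choices, the lists and the rule for named genes were fixed before the data were examined. The members were matched by symbol only, since the reference gave no product names, so genes with a bare locus number entered no list. Later, 8 false matches by the suffix of the symbol were removed from the lists (a thrombomodulin gene, 5 ribosomal S6 kinase genes, catb and rrm2b).

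The rule for named genes took, where no gene passed, the 5 genes with an informative symbol and the smallest p in each direction for 8% with 0% and 4% with 0%, as values only, the 2 members of a described list with the smallest p and the one with the highest mean, and a fixed panel of 15 genes. Of that panel, distal intestine had a tested gene for slc15a1, slc10a2, mmp9 and cd3e, and head kidney for fabp2, slc15a1, mmp9 and cd3e. The others had no gene with that symbol in the annotation or fell below the filter. Lists with fewer than 5 measured members, among them that for chitin digestion with 4 in each tissue, are given as levels without a test. Results of some genes that the rule or the tissue comparison would name are not reported here.

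The alternatives fixed beforehand were the DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, the run of fish numbers as a random block, counts summed per run, only the diets compared, each library left out in turn, the fish as a block across the tissues, and camera with an estimated or a preset correlation of 0.01 for the lists. Added after seeing the data were the fits without libraries that stood apart, the storage location as a covariate, the left-out libraries for the lists, the list test of the diet-by-tissue difference, and DESeq2 without libraries that stood apart. The low-count filter was run again in each edgeR and list fit with libraries left out, so the measured members of a list can differ. Other splits of the fish over the diets were drawn 70 times per tissue and 40 times for the fits of both tissues. A first draw of 100 splits per tissue took too long, was seen and was replaced. The share of variance by diet and by run was tested by permutation.

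The pairing was checked from the deviations of each library from its diet mean. Over 24826 genes the correlation between the 2 tissues of 1 fish ranged from 0.0292 to 0.359 (median 0.17), was over 0.1 in 16 of 18 fish, and was the highest of all pairings in 16 of 18. The procedures were tested on simulated counts drawn from the real means and library sizes with 50 genes changed per fold size. The changed genes were drawn from those with a mean over 1 CPM, so the shares recovered do not cover genes of lower level. In the simulated distal intestine comparison of 8% with 0% (27940 genes), edgeR recovered 12% of genes changed 1.5-fold, 54% at 2-fold, 86% at 3-fold and 90% at 4-fold, with 4 false calls. In head kidney (28019 genes) the shares were 14, 64, 78 and 80%, with 1 false call. DESeq2 recovered more, 22, 62, 92 and 92% in distal intestine and 22, 78, 88 and 84% in head kidney. It made 24 false calls among 28294 genes tested in the distal intestine simulation and 20 among 28329 in that of head kidney. With no change simulated edgeR called 0 genes in either tissue. For the diet-by-tissue difference at 8% (31823 genes), 24% of 2-fold and 84% of 4-fold differences were recovered. fry called the raised list in both tissues (adjusted p = 9.66e-09 and 7.83e-08) and 0 of 10 unchanged lists. Each gene was drawn on its own, without fish or run effects, and the lists held random genes, so their members were uncorrelated. The real lists had an estimated correlation of up to 0.782, for ribosomal proteins, and 0.487 for cholesterol, in distal intestine at 4% against 0%. The simulation therefore does not give the error rate of fry on the real lists.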

Results

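Messenger RNA was measured in the distal intestine and the head kidney of 18 Atlantic salmon. The fish ate feed with 0, 4 or 8% meal of black soldier fly larvae, an insect protein source, and the design asks how the transcripts of both organs respond to rising inclusion. Each diet had 6 fish, and each fish gave 1 library per tissue, so there were 36 libraries. Mean total counts per library in distal intestine were 15.01 ± 1.99, 14.419 ± 2.011 and 15.302 ± 1.959 M (mega) counts (SD, n = 6) on 0, 4 and 8%. In head kidney they were 14.958 ± 1.828, 12.885 ± 0.645 and 13.15 ± 1.806 M counts. All group values below are means over 6 fish with their SD, and all differences are log2 values with their SE, unless a sentence says otherwise.

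The tissues differed in 16464 of 32197 genes (edgeR, adjusted p under 0.05 and an absolute log2 difference over 1), with 8508 higher in distal intestine and 7956 higher in head kidney. Distal intestine had 14 of 16 genes of enterocyte absorption and the brush border higher, with a median log2 difference of 9.08. It also had 9 of 11 genes of cholesterol synthesis and uptake (median 3.19) and 10 of 11 tight junction genes (median 1.71) higher. Head kidney had 10 of 12 neutrophil and macrophage genes (median -5.15), 5 of 6 B cell genes (median -3.16), 5 of 9 T cell genes (median -2.01) and 6 of 7 erythroid genes (median -5.19) higher. Of the complement and antimicrobial genes, 10 of 11 were higher in head kidney and 1 in distal intestine (median -3.08). The cell cycle list had 11 of 16 genes higher in head kidney, and oxidative phosphorylation had 21 of 34 higher in distal intestine. Ribosomal protein genes mostly did not pass, with 1 of 44 called.

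Single genes given for the tissues were chosen after their values were seen. The trafficking adaptor hook1 had 276.9 ± 54.5 CPM in the 18 distal intestine libraries and 9.76 ± 1.54 in the 18 of head kidney. In the other direction, ptprc, the common leukocyte antigen CD45, had 114.7 ± 20.45 CPM in distal intestine and 894.3 ± 105.6 in head kidney. The integrin gene itb2 had 44.2 ± 10.2 and 760.5 ± 82.5 CPM. With the fish as a replicate block, which uses the pairing of the tissues, 16510 genes passed. On Ssal_v3.1, hook1 lies on chromosome 10 (29799489 to 29818735), ptprc on chromosome 10 (50257533 to 50282500) and itb2 on chromosome 25 (10073863 to 10096952).

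Within distal intestine, with marker genes chosen after their values were seen, the libraries of fish 6 and fish 7, both on 0%, stood apart from the other 16 on the first principal component, which held 19.8% of the variance. They had 2822.15 and 3353.88 CPM of fabp2, the intestinal fatty acid binding protein, where the other 16 libraries had at most 5.91. The peptide transporter slc15a1 had 263.96 and 251.4 CPM in them and at most 28.89 elsewhere. The receptor gene cubn, which serves protein uptake in the hind gut, had 2.18 and 26.5 CPM against 999 to 3200 in the others. The cathepsin gene ctsbb had 161 and 549 CPM against 4060 to 13500. Other single libraries also stood out. Fish 22 (4%) had 381.82 CPM of the neutrophil gene mmp9 and at most 115.04 was seen elsewhere. Fish 14 (8%) had 1781.62 CPM of the interferon-induced gene isg15, with at most 332.5 elsewhere. Fish 1 (4%) had 444 CPM of the smooth muscle gene acta2, with at most 221 elsewhere.

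**Figure D1:**
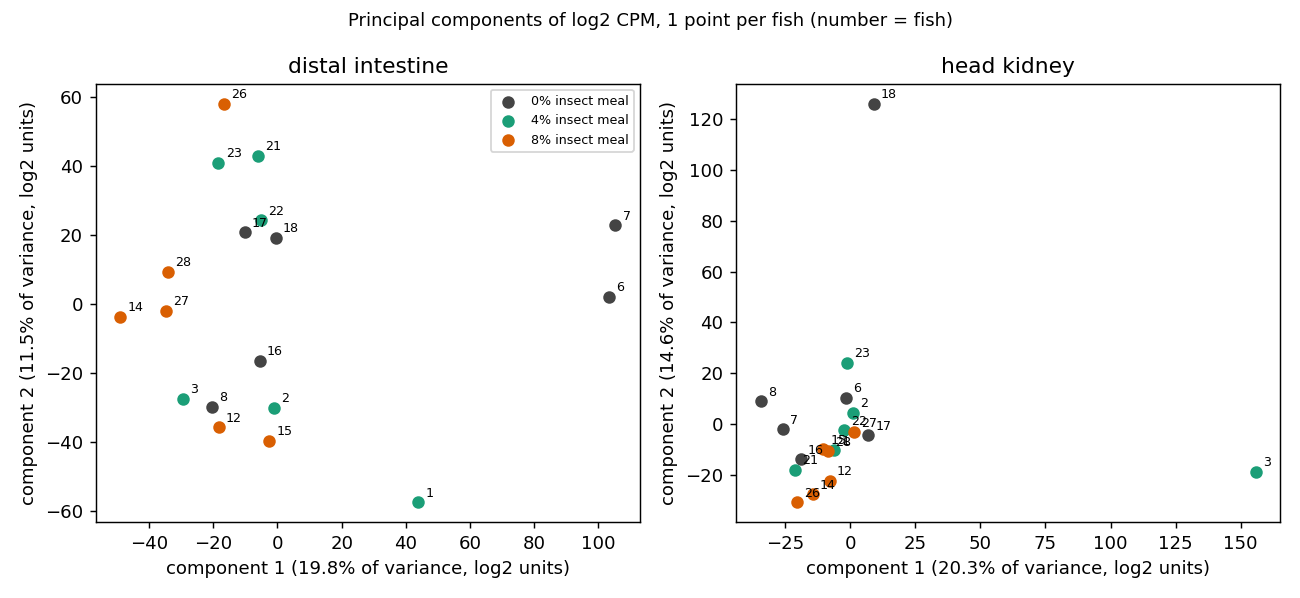
Position of each library on the first and second principal components of log2 CPM, in log2 units, by tissue, with a point and number for each fish and colour for the diet. In distal intestine the first component holds 19.8% and the second 11.5% of the variance, and fish 6 and 7 lie at 103.3 and 105.3 on the first. In head kidney the shares are 20.3 and 14.6%, with fish 3 at 155.8 on the first and fish 18 at 126.1 on the second.

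The share of variance that followed diet was 14.9% in distal intestine (permutation p = 0.0593) and 13.6% in head kidney (permutation p = 0.0683), where chance gives 11.8% in each. Both values miss the threshold. Runs of neighbouring fish numbers within a diet held 21.9% in distal intestine (exact p = 0.035, chance 17%) and 18.9% in head kidney (exact p = 0.065, chance 17.3%). With the 500 most variable genes, the distal intestine share by run was 19.2% (exact p = 0.346). With the runs kept whole, the share by diet had an exact p of 0.533 in distal intestine and 0.2 in head kidney, over 15 ways to give the 6 runs to the diets.

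In distal intestine, 8% insect meal was compared with 0% to ask about the highest inclusion. The gene with an informative symbol and the smallest p among those higher was wbp2, with 4.89 ± 0.448 CPM on 0%, 6.22 ± 1.35 on 4% and 8.4 ± 1.47 on 8% (0.78 ± 0.15). The next were fam168b at 7.42 ± 1.32, 11.3 ± 0.954 and 11.2 ± 0.665 CPM (0.59 ± 0.12), sez6l2 (2.71 ± 0.60), the intermediate filament gene vim at 7.29 ± 4.61, 21.1 ± 13.5 and 36.3 ± 23.9 CPM (2.32 ± 0.60), and the phosphatase gene mtm1 (0.41 ± 0.11). Lower were catk at 23.1 ± 2.4, 24.1 ± 1.01 and 16.7 ± 2.06 CPM (-0.47 ± 0.10), glipr1a (-0.75 ± 0.17), the fatty acid elongation gene tecrb (-0.51 ± 0.12), and alox5ap, needed for leukotriene synthesis, at 36.5 ± 3.74, 33.6 ± 9.93 and 21.6 ± 5.09 CPM (-0.76 ± 0.18). The gene arhgap24 (-2.84 ± 0.67) was also lower, with fish 6, 16 and 17 of the 0% diet at 9.03, 12.89 and 16.06 CPM. None of these genes passed the adjusted threshold in edgeR. Their places on Ssal_v3.1 are chromosome 28 for wbp2 (11548355 to 11559635), 29 for fam168b (33800658 to 33807255), 19 for vim (15232763 to 15240820), 5 for catk (59497395 to 59504329) and 11 for alox5ap (100648044 to 100656726).

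By gene group, none of 24 lists passed in this comparison of 8% with 0% in distal intestine. All 11 cholesterol genes were lower (mean -0.49, adjusted p = 0.267), and 3 passed when adjusted over the list alone against 0 over all genes. The synthase gene hmgcs1 was at -0.90 ± 0.27, and sc5d, the member with the highest mean, was at -0.47 ± 0.19 and did not pass. All 7 genes of fatty acid synthesis and desaturation were lower (mean -0.67, adjusted p = 0.267). With single libraries left out the mean was -0.87 to -0.47, with -0.47 without fish 7. Members of this list were the elongase gene elovl5 (-3.62 ± 1.21) and the desaturase gene scdb (-2.39 ± 1.03). Of these, elovl5 had 15.46 and 29.77 CPM in fish 6 and 7 and at most 2.88 elsewhere, and scdb had 367.74 and 601.32 CPM in them, with fish 22 (4%) at 921.57. Of 9 T cell genes 8 were lower (mean -0.37, adjusted p = 0.267, and -0.57 without fish 7), and 2 passed when adjusted over the list alone, cd3e (-0.40 ± 0.14) and prf1.3 (-2.59 ± 0.77). Of 5 B cell genes 4 were lower (mean -0.24, adjusted p = 0.267, and -0.14 without fish 8), with blnk at -0.43 ± 0.13, the 1 gene that passed over the list alone. Of 13 interferon response genes 12 were higher (mean 0.55, adjusted p = 0.486), with isg15 at 1.97 ± 0.71 and mx2 at 1.99 ± 0.76. Without fish 14, which had 1781.62 CPM of isg15, the mean was 0.06, isg15 was at 0.22 ± 0.36 and mx2 at 0.38 ± 0.50. Ribosomal proteins (42 of 44 lower, mean -0.21) and oxidative phosphorylation (33 of 34 lower, mean -0.19, and -0.11 without fish 7) both had adjusted p = 0.347.

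In distal intestine at 8% against 0%, edgeR called 0 of 28295 genes, with 2541 at an unadjusted p under 0.05 (1445 higher, 1096 lower) and a smallest adjusted p of 0.411. DESeq2 called 79 genes (23 higher, 56 lower), led by fabp2, alp3 and zgc:154142 at the levels of fish 6 and 7, and 4 without these fish, of which 2 were among the 79. Those 4, chosen after their values were seen, were arhgap24 (-3.04 ± 0.63), LOC106560296 (-1.04 ± 0.21), LOC100380447 (-2.72 ± 0.59) and LOC106584496 (-1.91 ± 0.41). The median gene had a 95% interval of 0.453 log2 units to each side, and 73.7% of genes had an interval within a 2-fold change.

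Of the fixed panel of genes in distal intestine, the ileal bile acid transporter slc10a2 had 2040 ± 746, 2510 ± 823 and 2760 ± 619 CPM on 0, 4 and 8%, and 0.43 ± 0.25 at 8% against 0%. For slc15a1 the means were 88.9 ± 131, 11 ± 9.65 and 6.94 ± 11.5 CPM. Its differences from 0%, -3.70 ± 1.48 at 8% and -3.01 ± 1.42 at 4%, turned to 0.64 ± 1.28 and 1.33 ± 1.30 without fish 6 and 7. The gelatinase gene mmp9 had 39.2 ± 29.7, 107 ± 139 and 21 ± 12.2 CPM, with fish 22 (4%) at 382 CPM. Its difference at 4% against 0%, 1.45 ± 0.70, ranged from 0.38 to 1.9 with single libraries left out. The T cell receptor component cd3e had 25.5 ± 2.68, 28.5 ± 6.16 and 19.3 ± 1.83 CPM. On Ssal_v3.1 slc10a2 lies on chromosome 21 (17505271 to 17510204), slc15a1 on chromosome 16 (96201653 to 96257201), mmp9 on chromosome 15 (101635925 to 101645092) and cd3e on chromosome 20 (54672272 to 54675144).

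Some lists had too few measured members for a test. Mean log2 CPM of the 4 chitin digestion and amino sugar genes in distal intestine was 7.38 ± 0.59, 7.66 ± 0.38 and 7.91 ± 0.14 on 0, 4 and 8%, and in head kidney 5.14 ± 0.20, 5.24 ± 0.24 and 5.05 ± 0.19. The 3 bile acid genes of distal intestine had 6.18 ± 0.19, 6.34 ± 0.23 and 6.43 ± 0.26. The 2 mucus genes had 10.0 ± 0.16, 9.97 ± 0.39 and 9.90 ± 0.40.

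The comparison of 4% with 0% in distal intestine asks about the lower inclusion. Genes of cholesterol metabolism led those lower. The synthase gene hmgcs1, which acts early in cholesterol synthesis, had 199 ± 60.4 CPM on 0%, 90.6 ± 24.6 on 4% and 107 ± 48.3 on 8% (-1.13 ± 0.28 at 4%). The thiolase gene acat2 had 58.2 ± 25, 29.8 ± 6.03 and 34 ± 6.56 CPM (-0.97 ± 0.23), and tmem97, a sterol-regulated membrane protein, 18.3 ± 7, 10.3 ± 1.19 and 11.1 ± 2.45 CPM (-0.84 ± 0.20). Also lower were tecrb (-0.48 ± 0.12) and the fatty acid desaturase gene fadsd6 (-1.79 ± 0.46), for which fish 6 and 7 had 463.2 and 517.09 CPM and the other 16 libraries 48.1 to 125.84. Higher were fam168b (0.60 ± 0.12), jelt at 7.49 ± 1.7, 14.7 ± 3.38 and 8.21 ± 2.86 CPM (0.97 ± 0.22), cep85l (0.63 ± 0.16), gpr34b (1.13 ± 0.33) and mip2a (1.14 ± 0.34). None of these passed the adjusted threshold in edgeR. On Ssal_v3.1 hmgcs1 lies on chromosome 1 (164248989 to 164264250), acat2 on chromosome 6 (73165639 to 73172319), fadsd6 on chromosome 23 (44931746 to 44945660) and jelt on chromosome 11 (70369550 to 70374091).

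As a group in distal intestine, all 11 cholesterol synthesis and uptake genes were lower on 4% than on 0%, with a mean of -0.63 and a median of -0.64, but the list did not pass (adjusted p = 0.0822). Adjusted over the list alone, 8 of the 11 genes passed, against 0 over all genes, among them lss (-0.80 ± 0.22) and sc5d (-0.56 ± 0.20). In camera with an estimated correlation, which sets the list against the other genes, the adjusted p was 0.192. The list level in log2 CPM was 5.80 ± 0.34, 5.17 ± 0.19 and 5.31 ± 0.39 on 0, 4 and 8%, and all 6 fish on 4% (4.88 to 5.40) lay below all 6 on 0% (5.53 to 6.34). The list passed when fish 28 of the 8% diet was left out (-0.65, adjusted p = 0.0452) and did not pass without fish 6 and 7 (-0.54, adjusted p = 0.357). Of the other groups, all 12 neutrophil and macrophage genes (mean 0.46), 7 of 8 complement genes (mean 0.34) and 7 of 9 T cell genes (mean 0.36) were higher on 4%, each with adjusted p = 0.392. These means were 0.22 without fish 22, -0.01 without fish 8 and 0.17 without fish 7. The filter was run again in these fits, so the measured members can differ. Interferon genes were higher in 12 of 13 (mean 0.76, adjusted p = 0.43), with irf7 at 1.19 ± 0.51. Cell cycle genes were lower in 16 of 16 (mean -0.36) and ribosomal proteins in 43 of 44 (mean -0.27), each with adjusted p = 0.392.

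At 4% against 0% in distal intestine, edgeR called 0 genes, with 1861 at an unadjusted p under 0.05 (976 higher, 885 lower) and a smallest adjusted p of 0.698. DESeq2 called 25 (9 higher, 16 lower), including hmgcs1, acat2, fadsd6, jelt and fam168b. Without fish 6 and 7 it called 6, of which 3 were among the 25 and none was among these 5 named genes.

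Between the diets with insect meal, 3 immune gene lists of distal intestine fell from 4 to 8%. The T cell list was lower on 8% in 8 of 9 genes, with a mean of -0.73 and a median of -0.53 (adjusted p = 0.0228 in fry, and adjusted p = 0.0585 in camera with an estimated correlation). Its level in log2 CPM was 1.85 ± 0.27 on 4% and 1.19 ± 0.09 on 8%, and all 6 fish on 8% (1.02 to 1.28) lay below all 6 on 4% (1.43 to 2.21). The 0% fish had 1.53 ± 0.40, with fish 7 at 0.79. The T cell receptor gene cd3e was at -0.56 ± 0.14 and the perforin gene prf1.3, of cytotoxic lymphocytes, at -2.71 ± 0.77. These were the 2 genes that passed when adjusted over the list alone, against 0 over all genes. The neutrophil and macrophage list was lower in 12 of 12 genes (mean -0.88, median -0.91, adjusted p = 0.0429 in fry, and adjusted p = 0.0875 in camera with an estimated correlation), at 4.72 ± 0.68 on 4%, 3.83 ± 0.32 on 8% and 4.25 ± 0.33 on 0%. Adjusted over the list alone, 7 of its genes passed, among them csf3r, the receptor for granulocyte colony-stimulating factor (-1.11 ± 0.30), and the collagenase gene mmp13 (-1.91 ± 0.53). Its most abundant gene, mpeg1.1, was at -0.53 ± 0.28 (-0.27 without fish 21) and did not pass. Complement and antimicrobial genes were lower in 8 of 8 (mean -0.65, median -0.66, adjusted p = 0.0429 in fry, and adjusted p = 0.0875 in camera with an estimated correlation), and 4 passed over the list alone, among them c1qb (-0.88 ± 0.20), c1qc (-0.55 ± 0.17) and cfd (-1.70 ± 0.53). Fish 22 (4%), whose neutrophil list level was 5.90 against 3.91 to 4.98 in the other 4% fish, also had 269.75 CPM of mmp13 and 485 CPM of cfd, with at most 92.8 and 167 elsewhere. Without fish 22 mmp13 was at -1.15 ± 0.40 and cfd at -0.90 ± 0.39.

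Other immune and stromal groups of distal intestine did not pass between 8 and 4%. B cell genes were lower in 4 of 5 (mean -0.46, adjusted p = 0.102, 0 over the list alone), and inflammatory cytokine genes in 5 of 6 (mean -0.32, adjusted p = 0.107), with tgfb1a, the 1 gene that passed over the list alone, at -0.52 ± 0.15. All 8 smooth muscle and stroma genes were lower too (mean -0.51, adjusted p = 0.858), and fish 1 had the highest level of that list, without which the mean was -0.24. Cholesterol genes were higher on 8% in 11 of 11 (mean 0.14, adjusted p = 0.858, and 0.05 without fish 26). Interferon genes were higher in 11 of 13 by edgeR, while the list mean was -0.20 (-0.68 without fish 14) and its test pointed down (adjusted p = 0.858). On Ssal_v3.1 prf1.3 lies on chromosome 3 (58451251 to 58455562), csf3r on chromosome 2 (40788265 to 40803979), mmp13 on chromosome 4 (53644671 to 53650937), c1qb on chromosome 11 (109954733 to 109976732) and cfd on chromosome 1 (2354582 to 2357873).

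The 3 immune means of distal intestine at 8% against 4% kept their size without any 1 library, at -0.83 to -0.63 for T cells, -1.05 to -0.67 for neutrophils and macrophages and -0.86 to -0.63 for complement, but none passed without fish 3, 14 or 26, where T cells were at -0.63, -0.74 and -0.71 (adjusted p = 0.0628, 0.0532 and 0.0517). Without fish 1, 6, 7, 14 and 22 the T cell list was at -0.72 (adjusted p = 0.0691), neutrophils and macrophages at -0.63 (0.152) and complement at -0.40 (0.403).

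Gene by gene at 8% against 4% in distal intestine, edgeR called 0 genes, with 2157 at an unadjusted p under 0.05 (612 higher, 1545 lower) and a smallest adjusted p of 0.243 for pln, which encodes phospholamban (-1.62 ± 0.27) and was chosen after its value was seen. DESeq2 called 95 genes, 89 of them lower on 8%, and without fish 6 and 7 it called 104, of which 78 were among the 95. Leukocyte genes were among its calls on all libraries, picked here after their values were seen. They were ptprc (-0.47 ± 0.11), the engulfment gene elmo1 (-0.61 ± 0.15), the myosin gene myo1f (-0.60 ± 0.15), rhog (-0.59 ± 0.15), c1qb (-0.87 ± 0.21), mmp13 (-1.91 ± 0.48), prf1.3 (-2.72 ± 0.71) and cd3e (-0.55 ± 0.15). Of these, mmp13 and cd3e were no longer called without fish 6 and 7, which ate the 0% diet and are on neither side of this comparison. Leaving out fish 23 gave 2 genes in edgeR, glipr1a (adjusted p = 0.0467) and LOC106589603 (-1.09 ± 0.15, adjusted p = 0.026).

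**Figure D2:**
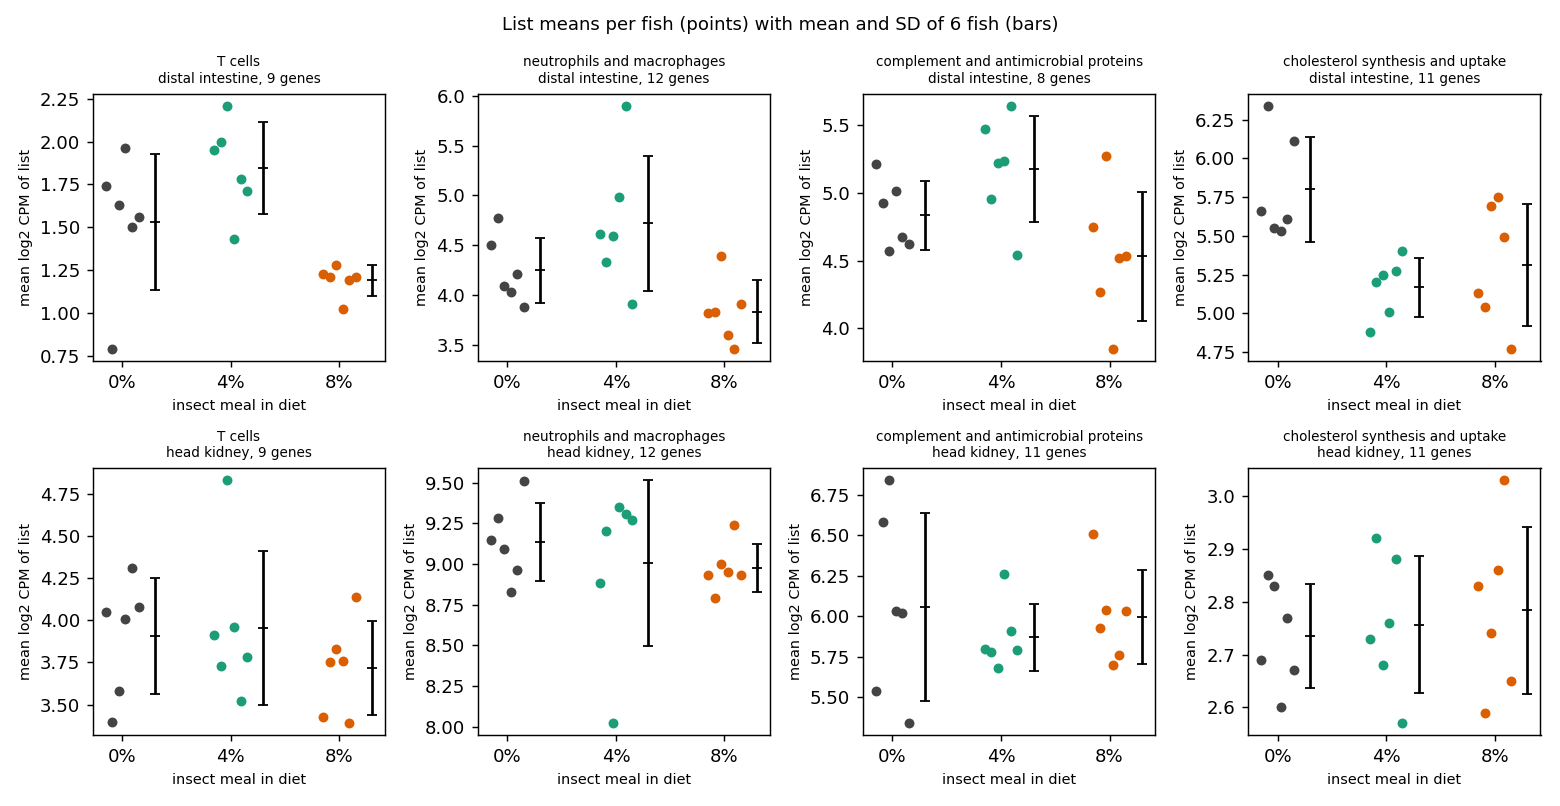
Mean log2 CPM of the member genes of each gene list shown, per fish (points), by diet and tissue, with bars for the mean and SD of 6 fish. In distal intestine the T cell list lies at 1.02 to 1.28 in the 8% fish and at 1.43 to 2.21 in the 4% fish, and the cholesterol list is highest on 0%.

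Along the dose in distal intestine, the slope of log2 expression per 1% of insect meal was 0.10 ± 0.02 for wbp2, 0.33 ± 0.07 for sez6l2 and 0.29 ± 0.07 for vim. For the cholesterol list all 11 genes had a negative slope (mean -0.06, adjusted p = 0.384), with 2 passing over the list alone, among them hmgcs1 (-0.11 ± 0.04). All 7 genes of fatty acid synthesis were also negative (mean -0.09, adjusted p = 0.384), led by elovl5 (-0.47 ± 0.14, and -0.31 ± 0.13 without fish 7), the 1 gene that passed over the list alone. With single libraries left out the mean of this list was -0.12 to -0.06, with -0.06 without fish 7. None of 24 lists passed. In edgeR 0 genes passed, with 2445 at an unadjusted p under 0.05 (1460 positive, 985 negative) and a smallest adjusted p of 0.397. DESeq2 called 72 (23 positive, 49 negative) and 0 without fish 6 and 7.

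In head kidney, the library of fish 3 (4%) stood apart on the first principal component, which held 20.3% of the variance. It had 120 CPM of mpx, the neutrophil myeloperoxidase, against 1990 to 4680 in the other 17, and 44.5 CPM of hce1 against 3800 to 10500. No count of rag1, the recombinase of developing lymphocytes, was found in it, which allows up to 0.225 CPM at its depth, where the others had 2.81 to 13.7. The leukocyte genes ptprc and itb2, at 1310 and 854 CPM, lay within the range of the others, while acta2 had 118 CPM against 3.93 to 10.2. Fish 18 (0%) had the fewest genes detected, 30652. Fish 27 (8%) had 1640 CPM of star and 1210.95 of hsd3b1, both genes of steroid synthesis, with at most 52.7 and 38.36 elsewhere. Fish 8 (0%) had 132.33 CPM of albumin, alb1, with at most 13.44 elsewhere. Fish 22 (4%) had 55.56 CPM of the brush border peptidase anpepa, with at most 2.38 elsewhere.

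For 8% against 0% in head kidney, higher genes were led by susd1 at 36.6 ± 7.75 CPM on 0%, 49.5 ± 4.41 on 4% and 57.5 ± 8.84 on 8% (0.65 ± 0.13). They went on with suco at 7.17 ± 2.21, 7.59 ± 1.54 and 13 ± 2.68 CPM (0.86 ± 0.20), wbp2 at 5.44 ± 1.3, 6.74 ± 2.17 and 9.75 ± 1.59 CPM (0.84 ± 0.22), and the mitochondrial mutase gene mmut (0.29 ± 0.07). The fifth, hsd3b1 (7.00 ± 1.77), had 1210.95 CPM in fish 27, and the difference without that fish was 2.51. Lower were tph2, a tryptophan hydroxylase gene of serotonin synthesis, at 13.6 ± 2.41, 12.6 ± 2.1 and 8.67 ± 0.82 CPM (-0.64 ± 0.14), the growth factor gene bmp2 (-1.18 ± 0.29), cp075 (-0.37 ± 0.09), the RNA polymerase subunit gene polr3k (-0.55 ± 0.14) and the mannosidase gene man2b2 (-0.35 ± 0.09). None of these passed in edgeR. On Ssal_v3.1 susd1 lies on chromosome 24 (27618236 to 27628077), suco on chromosome 10 (30871930 to 30961234) and tph2 on chromosome 10 (111394130 to 111404998).

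Erythroid genes of head kidney were higher on 8% than on 0% in 6 of 7 (mean 0.68, median 0.68, adjusted p = 0.59), and 0 passed over the list alone. The haemoglobin gene hba had 816 ± 629, 1787 ± 796 and 2215 ± 756.5 CPM on 0, 4 and 8% (1.44 ± 0.51 at 8%), and the erythroid transcription factor gata1 had 49.3 ± 17.5, 57.1 ± 16.4 and 76.8 ± 20.5 CPM (0.64 ± 0.24). The smallest adjusted p of a list was that of the circadian clock, 0.45 (mean 0.19, 9 of 14 higher), with per1b at 0.45 ± 0.18. All 44 ribosomal protein genes were lower (mean -0.19, adjusted p = 0.704, and -0.11 without fish 7), with rps19 at -0.40 ± 0.15. Complement genes were lower in 10 of 11, and their test pointed down while the mean was 0.11 (-0.08 without fish 18) and the median -0.22 (adjusted p = 0.704). Liver genes, a list of another cell type, were lower in 6 of 6 by edgeR while their mean on the voom scale was 0.94 (adjusted p = 0.826, and 0.09 without fish 18), with fish 8 of the 0% diet at a list level of 6.88 log2 CPM and at most 3.70 elsewhere. In head kidney hba lies on chromosome 6 (37638473 to 37639361), gata1 on chromosome 12 (79154094 to 79174094) and per1b on chromosome 7 (7965313 to 7987461).

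At 8% against 0% in head kidney, edgeR called 0 of 28331 genes, with 2648 at an unadjusted p under 0.05 (1519 higher, 1129 lower), a smallest adjusted p of 0.512 and a median 95% interval of 0.411 log2 units to each side. DESeq2 called 12, including susd1 and tph2, and 16 without fish 3 and 18, 5 of them shared. Counts summed per run of fish numbers gave 1 gene, LOC106599076 (4.65 ± 0.38).

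The 4% with 0% comparison in head kidney had rif1, a regulator of replication timing, first among the lower genes, at 50.4 ± 4.24, 34.3 ± 5.46 and 50 ± 6.19 CPM on 0, 4 and 8% (-0.55 ± 0.11). The integrin gene itga3b (-1.15 ± 0.26) was lower, as were genes of RNA processing and histone modification, thg1l (-0.47 ± 0.12), gar1 at 65.8 ± 12.4, 47.1 ± 6.79 and 48.8 ± 6.44 CPM (-0.48 ± 0.13), and riox2 (-0.35 ± 0.10). Higher were ppfibp2b (1.86 ± 0.45), anpepa (3.36 ± 0.92), the acute phase gene saa5 (2.31 ± 0.65), the chemokine receptor gene ccr12a (1.06 ± 0.30) and rnf144aa (0.84 ± 0.24). Of these, anpepa had 55.56 CPM in fish 22 and was at 0.64 without it, and saa5 had 53.93 CPM in fish 3 and was at 0.87 without it. None passed in edgeR. On Ssal_v3.1 rif1 lies on chromosome 25 (21993913 to 22020425) and itga3b on chromosome 19 (55744570 to 55802218).

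Immediate early and handling stress genes of head kidney were higher on 4% in 10 of 12 (mean 0.24, median 0.25, adjusted p = 0.673), with jun at 0.83 ± 0.32 (0.52 ± 0.28 without fish 3), and 0 passed over the list alone. Genes of the enterocyte list were higher in 6 of 7 (mean 0.69, adjusted p = 0.864), and 4 passed over the list alone, among them slc3a1 (2.12 ± 0.70) and vil1 (1.06 ± 0.36). Without fish 22 the mean was 0.40, slc3a1 was at 0.38 ± 0.40 and vil1 at 0.47 ± 0.23. Of 9 tight junction genes 7 were higher (mean 0.11, adjusted p = 0.957), and cldn15la (3.69 ± 1.09) passed over the list alone, with fish 22 at the highest list level, and without this fish they were at -0.05 and 0.55 ± 0.59. Inflammatory cytokine genes were higher in 4 of 5 (mean 0.46, adjusted p = 0.874), with saa5 passing over the list alone and fish 3 at the highest level of the 4% fish, and the mean was 0.24 without fish 3. Liver genes were lower in 6 of 6 (mean -1.91, adjusted p = 0.949), and all 6 passed over the list alone, with alb1 at -3.98 ± 1.36 and tfa at -1.53 ± 0.60. Without fish 8 of the 0% diet, which had 132.33 CPM of alb1, the mean was -1.01, alb1 was at -1.62 ± 1.07 and tfa at -0.44 ± 0.41. Cell cycle genes were lower in 15 of 16 (mean -0.30, adjusted p = 0.864), with mcm6 at -0.46 ± 0.17, and fish 3 had the lowest level of that list, without which the mean was -0.04 and mcm6 at -0.32 ± 0.13. Neutrophil and macrophage genes were split, 6 higher and 6 lower (adjusted p = 0.957). Antigen presentation genes had a mean of -0.24 (-0.10 without fish 1) with a test that pointed up (adjusted p = 0.957).

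At 4% against 0% in head kidney, edgeR called 0 genes, with 1797 at an unadjusted p under 0.05 (1052 higher, 745 lower) and a smallest adjusted p of 0.783. DESeq2 called 13, including rif1, and 10 without fish 3 and 18, with 5 shared. Leaving out fish 1 gave 1 gene in edgeR, LOC106594049 (1.85 ± 0.26), and counts summed per run of fish numbers gave LOC123729671 (adjusted p = 0.0199), both chosen after their values were seen.

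Between 8 and 4% in head kidney, all 16 cell cycle genes were higher on 8% (mean 0.38, adjusted p = 0.443), with mki67, a marker of dividing cells, at 0.51 ± 0.23. Fish 3, on 4%, had the lowest level of this list, and without it the mean was 0.13 and mki67 at 0.33 ± 0.15. Immediate early genes were lower in 10 of 12 (mean -0.21, adjusted p = 0.352), and 3 passed over the list alone, among them dusp1 (-0.46 ± 0.13) and klf2a (-0.50 ± 0.16, and -0.33 ± 0.13 without fish 3), against 0 over all genes. Complement genes were lower in 9 of 11, with c1qb at -0.65 ± 0.23 (-0.42 ± 0.20 without fish 3) and cfd at -0.57 ± 0.18, and their test pointed down (median -0.25, adjusted p = 0.352) while the mean was 0.33. Inflammatory cytokine genes were lower in 5 of 5 (mean -0.53, adjusted p = 0.443, and -0.31 without fish 3). For this list fish 3 had a level of 5.43 log2 CPM against at most 4.25 in the other 4% fish, and it had 1523.14 CPM of c1qb, with at most 868.42 elsewhere. T cell genes were lower in 8 of 9 (mean -0.24, adjusted p = 0.619, and -0.07 without fish 3), with prf1.3 at -0.86 ± 0.30. Enterocyte genes were lower in 7 of 7 (mean -0.71, adjusted p = 0.443), 5 of them past the threshold over the list alone, and the mean was -0.41 without fish 22.

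At 8% against 4% in head kidney, edgeR called 0 genes, with 2706 at an unadjusted p under 0.05 (1266 higher, 1440 lower) and a smallest adjusted p of 0.501 for crym, a thyroid hormone binding protein (-0.73 ± 0.15, chosen after its value was seen). DESeq2 called 1, LOC106563633 (adjusted p = 2.9e-05), chosen after its value was seen, and 5 others without fish 3 and 18, which were rif1 (0.46 ± 0.10), mag (-0.52 ± 0.11), LOC123729671, LOC106573649 and LOC106611589. Counts summed per run gave 2, LOC123729671 and LOC106599076.

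Along the dose in head kidney the slope per 1% of insect meal was 0.08 ± 0.02 for susd1, 0.18 ± 0.07 for hba and 0.08 ± 0.03 for gata1. Erythroid genes had 6 of 7 positive slopes (mean 0.08, adjusted p = 0.58), clock genes 9 of 14 (mean 0.02, adjusted p = 0.391) and ribosomal proteins 44 of 44 negative (mean -0.02, adjusted p = 0.661, and -0.01 without fish 7). Over the list alone, the desaturase gene scdb (-0.04 ± 0.01) and the tight junction gene marveld3 (-0.19 ± 0.06) passed, against 0 over all genes. None of 24 lists passed. In edgeR 0 genes passed, with 2625 at an unadjusted p under 0.05 (1530 positive, 1095 negative) and a smallest adjusted p of 0.493. DESeq2 called 6 and 19 without fish 3 and 18, including all 6, susd1 among them. Leaving out fish 27 gave 1 gene, LOC106574049 (0.10 ± 0.02).

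Of the fixed panel in head kidney, mmp9 had 6450 ± 1290, 6580 ± 3610 and 5520 ± 662 CPM on 0, 4 and 8%, and cd3e 71.3 ± 23.1, 71.5 ± 28.8 and 59.9 ± 14.8. At 8% against 0% they were at -0.22 ± 0.33 and -0.25 ± 0.25. For fabp2 the means were 2.36 ± 1.01, 4.9 ± 8.59 and 1.17 ± 0.558 CPM, with fish 3 at 22.39 and a difference of 1.06 ± 0.73 at 4% that turned to -0.73 without that fish, and slc15a1 had 0.606 ± 0.412, 1.2 ± 0.539 and 0.572 ± 0.426.

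**Figure D3:**
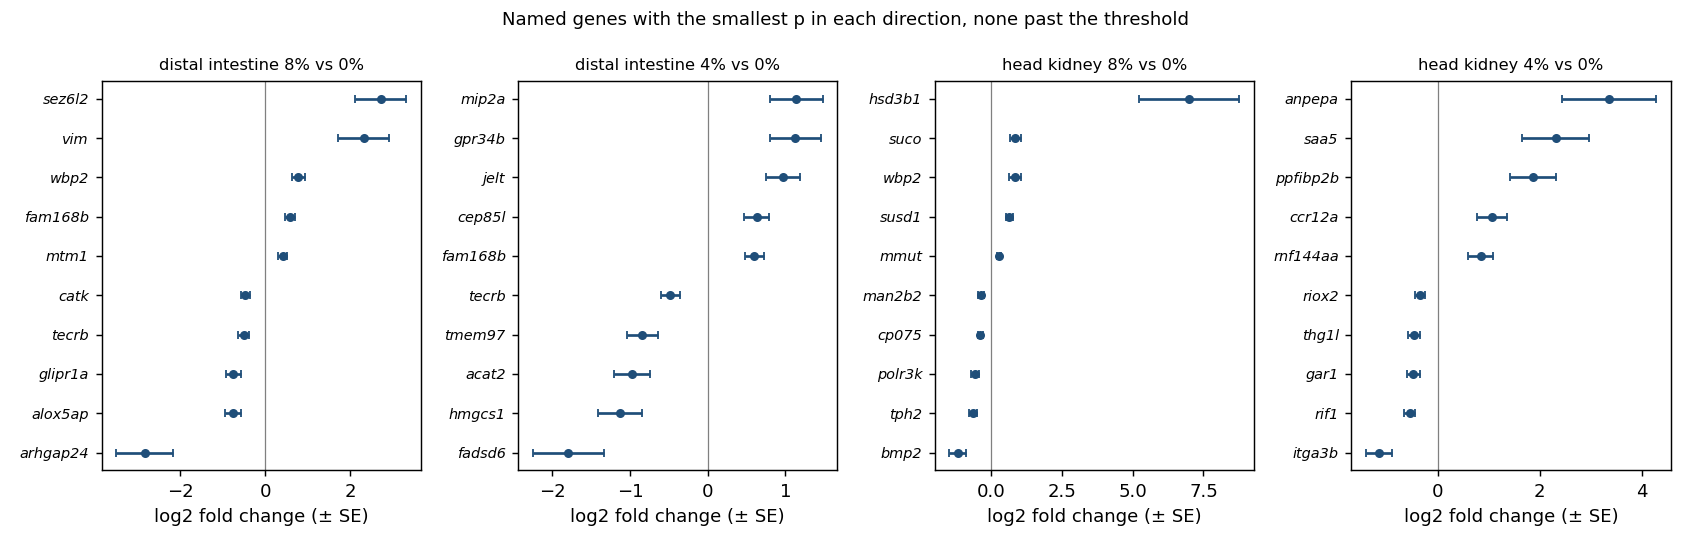
Log2 fold change of the named genes with the smallest p in each direction (points, with the SE as bars), for 8% and 4% against 0% in each tissue. None of these genes passed the adjusted threshold, and hsd3b1, at 7.00 ± 1.77 in head kidney, was at 2.51 without fish 27.

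Whether the diets acted differently on the tissues was tested as the difference between their diet effects. In edgeR 0 of 32197 genes passed at 8% against 0%, with 2088 at an unadjusted p under 0.05 and a smallest adjusted p of 0.402 for fabp2. At 4% against 0% it was 0 as well, with 1915 and a smallest adjusted p of 0.188 for cdh17. In head kidney fish 22 had 28.6 CPM of cdh17, with at most 1.77 elsewhere, and the difference of -6.75 ± 1.34 was -3.71 ± 0.79 without both libraries of this fish. For fabp2 the difference of -12.60 ± 2.62 at 8% was -2.79 ± 1.39 without those of fish 3, 6 and 7. With the fish as a replicate block, which uses the pairing, both counts were 0, with 1999 and 1698 at an unadjusted p under 0.05. The cholesterol list was lower in distal intestine relative to head kidney at 4% with adjusted p = 0.208, and 0.0507 with the block. The neutrophil and complement lists at 8% against 4% had adjusted p = 0.468 each and the T cell list 0.869, so a difference between the tissues in these groups was not shown. This list test was added after the data had been seen.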

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

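The tests of body site, depth, exchange and spleen for single libraries, of the 5 libraries left out together, of the size of the 3 immune lists without 1 library, and of alike fish within a run were chosen after the results they bear on had been seen. The rule that picks 10 markers per tissue and the criterion for HOX genes were also changed after a first result, and an earlier idea that fish 3 holds mostly another tissue was replaced untested by that of spleen. The 10 markers of a tissue were the named genes with the largest difference between the tissues among those with a mean of at least 100 CPM there. They were taken from these same libraries, those that stood apart included.

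A gap rule for a sample far from the other 5 of its group was applied to list levels in log2 CPM and to genes detected. It marked 16 of 156 groups, where chance flags about 1 in 20 groups. In distal intestine on 4%, fish 2 was lowest for enterocyte genes, 6.12 (nearest 6.72), and highest for oxidative phosphorylation, 5.80 (nearest 5.59). On 8%, fish 26 was lowest for T cells, 1.02 (nearest 1.19), fish 14 highest for the interferon response, 7.60 (nearest 5.24), and fish 12 highest for ribosomal proteins, 8.15 (nearest 7.79). In head kidney on 0%, fish 18 had 30652 genes detected (nearest 35802), and on 4% fish 23 had 34111 (nearest 35584). Fish 3 on 4% was highest for T cells, 4.83 (nearest 3.96), cytokines, 5.43 (nearest 4.25), and smooth muscle, 5.31 (nearest 3.98). It was lowest for the cell cycle, 4.55 (nearest 5.85), and for neutrophils and macrophages, 8.02 (nearest 8.88). Fish 21 was highest for fatty acid synthesis, 4.66 (nearest 4.23), and liver genes, 3.12 (nearest -0.17), fish 22 for tight junctions, 2.31 (nearest 1.44), and on 8% fish 27 for antioxidant defence, 5.41 (nearest 5.12).

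The distal intestine libraries of fish 6 and 7 had high fabp2 and slc15a1 and low cubn, lrp2b and ctsbb. Low depth is argued against by the total counts. Fish 6 had the highest of the tissue, 18596253, and fish 7 had 13902834, against a median of 14.725 M and a lowest of 11.673 M. The test of depth summed the HOX genes of groups 10 to 13, at 28.2% of what the depth gives (26.5 to 29.9 by counting error alone). The other 16 libraries had 58.4 to 157%. These genes are part of the pattern and the share is scaled to the depth, so it does not bear on depth. Exchange with a head kidney library is argued against, with 0 of 10 head kidney markers within the range of that tissue in both. These markers were picked from data that include both libraries. A more anterior stretch of intestine may be the source and stays open. Of the HOX genes above 0 in each of the other 16 libraries, 5 of 10 of groups 10 to 13, 3 of 4 of group 9 and 6 of 21 of groups 1 to 8 lay under the lowest of those libraries in both, and 0, 0 and 2 (hoxb3a and hoxb4aa) lay above the highest, where the test asked for fewer low genes of groups 1 to 8. The design gives no group that sets these fish apart from the others of their diet, so no biological difference between the fish was tested.

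The head kidney library of fish 3 had low mpx, hce1 and rag1 with ptprc and itb2 in the range of the others. Low depth is argued against by the total of the library, 13680777 counts, above the tissue median of 13.336 M. In the test of depth, 10 head kidney markers together were at 27.6% of what the depth gives (27.3 to 27.8 by counting error alone). The other 17 libraries had 84.1 to 128%. Of the 10 markers, 6 lay under the lowest of these libraries, 3 in their range and f13a above the highest. The sum includes hce1 and mpx, which are part of the pattern, and it is scaled to the depth, so it does not bear on depth. Exchange with an intestine library is argued against, with 0 of 10 intestine markers in the range of that tissue. Spleen in place of head kidney is a candidate explanation, as a hypothesis, because all 3 measured genes of a list of 6 spleen markers lay above the highest of the other 17 libraries. These were nkx23 at 43.7 CPM, nkx3-2 at 19 and tcf21 at 28.2, of which distal intestine expresses nkx23 at a mean of 9.57 CPM, and no biological difference between this fish and others was tested.

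Of the 3 immune lists lower at 8% than at 4% in distal intestine, T cells had an adjusted p of 0.0371 in fry with the run as a random block. The test had set such a call against alike fish within a run as the source, while the other 2 lists had 0.087 and did not pass. The block takes a single correlation over all genes, from 2 runs per diet, so the test cannot exclude alike fish within a run for these lists. By the rule fixed beforehand, a single library is the source if leaving it out ends the calls of all 3 lists. That happened in 3 fits, those without fish 3, 14 or 26, with fewer fish, so this rule came out for a single library. A size criterion written afterwards came out against it for T cells, with at least 87.4% of the mean left in each of 18 fits. The T cell level difference at 8% was -0.58 ± 0.11 (interval -0.86 to -0.31) without fish 3 against -0.66 ± 0.12 with all. The size of the T cell difference thus did not rest on 1 library, while its call depended on single libraries. For neutrophils and complement at least 75.9 and 98.2% was left, in fits whose measured members can differ. The interval reached 0 without some libraries, so that stays open. Without the 5 libraries that stood apart the T cell mean was -0.72 against -0.73, with a level difference of -0.65 ± 0.18 (interval -1.18 to -0.13). The T cell list no longer passed in fry (adjusted p = 0.0691), where the test asked for a call to argue against these libraries. So the T cell difference kept its size without them, but the test leaves them open as a source. Neutrophils and macrophages went to -0.63 and complement to -0.40, so there a part stays open too. Of 70 splits of single fish, 2 gave as many lists, with 3 in the real split and 3 as the highest of the others. This comparison was singled out because lists had passed in it. In each comparison of both tissues, 1 to 4 of the other splits gave a list past the threshold, so chance is not excluded. These splits also part the runs, and splits that keep the runs whole were not fitted. An effect of diet on these cells or their number stays open, untested.

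For the other diet results the real count past the threshold was 0, which each of the 70 splits of the fish over the diets reaches. This count therefore decides nothing about chance there. The highest counts of genes in another split were 1, 4, 19 and 11 in distal intestine for 8% against 0%, 4% against 0%, 8% against 4% and the dose slope, and 1, 2, 7 and 1 in head kidney. Of the other splits, 4 gave any gene for 8% against 4% and 3 for the dose slope in distal intestine, and what sets the splits with 19 and 11 genes apart was not tested. The highest counts of lists were 1, 4 and 2 in distal intestine for 8% against 0%, 4% against 0% and the dose slope, and 2, 1, 1 and 2 in head kidney. The splits also gave counts of genes at an unadjusted p under 0.05 in edgeR. As many as in the real split were reached by 6, 17, 11 and 6 of 70 in distal intestine, in the order given for the genes. In head kidney it was 11, 19, 6 and 14 of 70. The median of the other splits was 1377, 1339, 1351 and 1374 genes in distal intestine and 1364, 1234, 1427 and 1484 in head kidney. These counts do not exclude chance. For the diet-by-tissue difference all 40 of 40 splits likewise reached the real 0, with 1 gene as the highest of the others at 8% and at 4%. For the comparison of the tissues chance can be excluded, with 16464 genes in the real split, reached by 1 of 40, and 6205 as the highest of the others.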

How the results depend on the processing

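The fits without libraries apart (those of DESeq2 included), the storage location as a covariate, single libraries left out for the lists and the list test across tissues were added after the data had been seen. The other alternatives were planned. None of the counts and of the list differences given in this part changed direction. Many other lists without a call changed sign without 1 library, and only examples are given here. Against 0%, complement turned from 0.34 to -0.01 in distal intestine at 4% without fish 8 and from 0.11 to -0.08 in head kidney at 8% without fish 18. Enterocyte genes in distal intestine turned from 0.03 to -0.56 at 8% and from 0.05 to -0.37 at 4% without fish 8. In head kidney at 4%, tight junctions turned from 0.11 to -0.05 without fish 22, T cells from 0.06 to -0.12 and neutrophils and macrophages from -0.13 to 0.07 without fish 3. The measured members can differ between these fits, so such a turn need not come from the level of that fish. At 8% against 4% in distal intestine, leaving out fish 8, of the 0% diet, moved the complement mean from -0.65 to -0.73. Among named genes without a call, slc15a1 in distal intestine turned from -3.70 to 0.64 at 8% and from -3.01 to 1.33 at 4% without fish 6 and 7, and fabp2 in head kidney at 4% from 1.06 to -0.73 without fish 3. In head kidney slc15a1 at 8% (-0.04), mmp9 at 4% (0.03) and cd3e at 4% (0.01) lay near 0 and had either sign. Of 1621 values of 56 named genes by comparison, 1537 stayed within 1 SE, 64 moved by more and 20 went past the threshold. Most of these values come from fits with a single library left out, which moves a value little. In distal intestine, 11 of 28 values moved by over 1 SE in edgeR without fish 6 and 7, and 13 of 28 without fish 1, 6, 7, 14 and 22. In head kidney 2 of 28 did so without fish 3 and 18.

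DESeq2 called 79, 25, 95 and 72 genes in distal intestine (8% against 0%, 4% against 0%, 8% against 4%, dose slope) and 12, 13, 1 and 6 in head kidney, against 0 in edgeR. Without fish 6 and 7, or fish 3 and 18, it called 4, 6, 104 and 0, and 16, 10, 5 and 19. Counts summed per run called 1, 1 and 2 genes in the 3 head kidney comparisons. With single libraries left out, edgeR called 0 to 2 genes for distal intestine 8% against 4% (2 without fish 23), 0 to 1 for head kidney 4% against 0% (1 without fish 1) and 0 to 1 for its dose slope (1 without fish 27). The cause was not tested.

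With camera at a preset correlation, 10, 7, 6 and 9 lists passed in distal intestine and 3, 4, 7 and 3 in head kidney, and with an estimated correlation 0. The cholesterol list at 4% against 0% in distal intestine was at -0.63 with the preset correlation (adjusted p = 1.36e-11) and at -0.71 to -0.53 with single libraries left out (adjusted p 0.0452 to 0.228, 1 list past without fish 28, 0 to 1 in all). Over its alternatives the adjusted p reached 0.677.

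For 8% against 4% in distal intestine, 3 lists passed in fry, 0 in camera with an estimated correlation, 1 with the run as a random block, 0 without the 5 libraries apart and 0 to 4 with single libraries left out. Of the 3 immune lists, none passed without fish 3, 14 or 26, and 1 without fish 1, 7, 12, 16, 18, 21, 22, 27 or 28. T cells were at -0.73 with an estimated correlation (adjusted p = 0.0585), at -0.72 without the 5 libraries (0.0691) and at -0.83 to -0.63 with single libraries left out (0.00594 to 0.0628). Neutrophils and macrophages were at -0.88 with an estimated correlation (adjusted p = 0.0875) and with the run block (0.087), at -0.63 without the 5 libraries (0.152) and at -1.05 to -0.67 (0.0123 to 0.108). Complement was at -0.65 with an estimated correlation (adjusted p = 0.0875) and with the run block (0.087), at -0.40 without the 5 libraries (0.403) and at -0.86 to -0.63 (0.0123 to 0.105). Leaving out libraries leaves fewer fish, and the cause of these changes was not tested. The share of variance by run in distal intestine was 19.2% with the 500 most variable genes.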

Other observations

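The comparison of tap2b classes and the splits that pair tissues of different fish were chosen after the values had been seen. In distal intestine, 5 of 7 genes of xenobiotic metabolism were higher at 8% than at 0% (mean 0.20, adjusted p = 0.347, and 0.12 without fish 7). The kidney tubule list, 5 genes that the intestine also expresses, was at 4.51 ± 1.20, 5.09 ± 0.40 and 5.49 ± 0.41 log2 CPM (SD, n = 6) on 0, 4 and 8% (adjusted p = 0.347 at 8% against 0%), in a 0% group that holds fish 6 and 7. Its mean difference at 8% was 1.16, and 0.65 without fish 6, while 2 genes were higher and 3 lower, with a median of -0.0047. Tight junction genes were higher at 4% than at 0% in 9 of 11 (mean 0.16, adjusted p = 0.392, and 0.10 without fish 22). In head kidney, genes of the unfolded protein and amino acid stress response were higher at 8% than at 0% in 10 of 11 (mean 0.20, adjusted p = 0.806, and 0.13 without fish 12). Of fatty acid synthesis in head kidney, scdb was lower at 8% (-0.32 ± 0.10), the 1 gene that passed when adjusted over the list alone, while the list did not (adjusted p = 0.806). Heat shock protein genes had adjusted p = 0.396 in distal intestine and 0.806 in head kidney at 8% against 0%. The 2 interrenal genes had 1.28 ± 1.56, 1.23 ± 1.49 and 2.48 ± 2.28 log2 CPM in head kidney on 0, 4 and 8%, and the 2 skeletal muscle genes 0.94 ± 0.81, 0.62 ± 1.08 and 1.38 ± 0.72.

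Of 24826 genes measured in both tissues, 209 had a level across the 18 fish, after removal of the diet means, that correlated at r over 0.8 between the tissues. Chance can be excluded by 100 splits that pair the tissues of different fish, with 209 genes in the real pairing, reached by 1 of 100, and 18 as the highest of the others. Inherited differences between the fish are a candidate explanation, as a hypothesis. The test was whether these genes lie near each other, and 27 had a neighbour among them within 100 kb, where 1000 random sets of as many genes had a median of 6 and at most 20. Carry-over of RNA from the intestine into the head kidney library of a fish is argued against. Intestine markers in the head kidney of the same fish were at a median of 0% of their intestine level. Fish 22 had 1.48% and the next fish 0.0437%. These markers were chosen for their large difference between the tissues in these same libraries, which favours low values. Carry-over from the intestine would still raise them. Carry-over in the other direction was not tested.

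Among them were the antigen peptide transporter genes tap2b and abcb3. As a share of the counts of both genes, tap2b fell in 3 classes, with 4 fish at 0 to 0.865%, 11 at 45.2 to 63.8% and 3 at 99.7 to 100%. That 18 of 18 fish had the same class in both tissues follows from the choice of genes alike in both and decides nothing about a cause. Whether these are 2 forms of 1 gene stays open, and no genotype was analysed here.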
